A study of Mus musculus with 2 samples.

How the data were processed

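ChIP-seq with an antibody against H3K9me3 was performed on pooled intestines of mouse embryos at day 15.5, with 2 biological replicates of 78 and 62 embryos and DNA fragments of 300 to 500 bp, per the labels. The files analysed were 4 lists of narrow peaks on the mm10 assembly. Per the file headers, meaning the lists of contents deposited with each sample, 1 list was called for each replicate from its filtered alignments against a control, with a different control for each replicate. Another was called from the alignments of both replicates and both controls together, and the list of replicated peaks was derived from both replicates' lists and the pooled list. The aligner, the peak caller, their versions and the rule that selected replicated peaks are not given in the sources used here. Signal tracks and control libraries were not analysed here.

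Per the file headers the lists are in narrowPeak layout, from which the meaning of each column was taken. Column 7, the authors' enrichment value of a peak, was read here as a linear fold enrichment over its control. The peak caller, which sets that unit, is not given. Columns 8 and 9 hold −log10 of the peak's p-value and q-value as deposited by the authors; the lowest −log10 p was 2.01, and peaks with high q were kept in the lists. Column 10, the offset of the summit from the peak's start in bp, was deposited by the authors and was not used in any result. No further normalization was applied. A peak list gives no read counts, so no interval or floor that needs depth was computed. Each replicate was set against its own control in the authors' calls, so differences between the lists can come from the controls as well as from the tissue.

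The reference was GRCm38.p6, the assembly also named mm10, with GENCODE release M21. Chromosome names matched and 0 peaks lay beyond the end of any of the 21 chromosomes. Names of scaffolds in the peak lists could not be paired with names in the reference, so tests used chromosomes 1 to 19 and X, within the assembled part of each. Coordinates are 1-based. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9. Overlap counts under all 3 overlap rules were equal to those of bedtools 2.31.1.

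Chance was estimated by circular shifts. All peaks of a chromosome were moved together by a random distance of at least 1000000 bp and wrapped around the assembled span, 10000 times, which keeps the spacing of peaks and of genes. Two-sided p was the smaller tail doubled, counting the observed set among the shifts. Overlap between replicates (at least 1 bp) was tested one-sided with replicate 2's peaks shifted. Correlation of fold enrichment was computed over overlapping pairs, and its 95% interval treats pairs as independent. Peak midpoints were assigned to promoter (within 1000 bp of a transcript start of a protein-coding gene), exon, intron or intergenic sequence in that order, with Benjamini-Hochberg adjustment over the 4 classes. For each of 15 gene lists the number of members with a peak in the gene body or within 2000 bp was counted, with Benjamini-Hochberg adjustment over the 15 lists and a threshold of adjusted p 0.05. Lists covered Zfp, olfactory and vomeronasal receptor, clustered protocadherin, Hox, X-linked, ribosomal protein, imprinted and germline genes, intestinal epithelium, mesenchyme and smooth muscle, enteric nervous system, blood and endothelium, other organs, and the H3K9 methylation machinery. Last-exon enrichment was tested one-sided by redrawing each midpoint uniformly within its gene 10000 times. Soft-masked and G+C content were compared over 1000 shifts.

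Genes were named by a rule. It took the 4 members with the highest fold enrichment from each list past the threshold, 2 from every other list with a peak, and up to 12 imprinted genes. It added the 10 genes with the highest fold enrichment at a transcript start, the 10 with the most bases under peaks and the 5 densest windows of 1000000 bp. A peak described as at a transcript start came within 1000 bp of one and need not overlap it. The gene lists, tests, naming rule and the alternatives below, unless said otherwise, were fixed before the data were examined. Mroh2a, Trpm8, Ugt1a1, Ugt1a2, C230088H06Rik, Zfp933, Zfp978, Zfp984, Zfp985, 2700054A10Rik, Smok2a, Smok2b, Sfi1 and Drg1 were named as genes inside those windows, and were chosen after their values were seen.

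For every peak, 32-base words starting at every 4th base were looked up in the chromosomes and scaffolds of the assembly on both strands, and the percent that occurred more than once was recorded. Of the 1802 replicated peaks on chromosomes 1 to 19 and X, 1365 (75.7%) had at least 90% of their words occurring once.

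The tests were checked on simulated peaks. In 40 sets of shifted peaks with nothing added, 2.17% of 600 list tests had a permutation p of at most 0.05 and 0 lists passed the adjusted threshold. With a peak added to 20% of the members of each list in turn, 13 of 15 lists were recovered, and the 2 missed were clustered protocadherin and enteric nervous system genes. With 5% of replicate 2 peaks moved onto replicate 1 peaks, 5.20% were found overlapping.

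Alternatives to the main settings were a stricter threshold (q of at most 0.01), overlaps of at least 50% of the shorter or of both peaks, equal numbers of peaks per list, merging of peaks within 1000 bp, random placement of peaks 1000 times, promoters of 2000 bp, gene bodies or transcript starts alone, gene sets matched on length, the pooled list, and each replicate's own list. Added after seeing the data were peaks on unique sequence, replicated peaks present in each replicate's own list, and gene sets matched on both length and G+C content of the 2000 bp around the gene start.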

Results

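H3K9me3, the trimethylated form of lysine 9 of histone H3 that marks heterochromatin, was mapped by ChIP-seq in the intestine of B6NCrl mouse embryos at embryonic day 15.5. The series has 1 group with 2 biological replicates. Each replicate was a pool of intestines from embryos of both sexes, 78 embryos for replicate 1 and 62 for replicate 2. No second tissue, age or treatment is in the series, so the comparisons made here were between the replicates, and between the peaks and the genome. The values analysed were the authors' peak lists on mm10: 14198 peaks in replicate 1, 9350 in replicate 2, 19060 from the pooled reads and 1948 that the authors list as replicated. Peak lists hold no read counts, so the depth of each library is unknown here. The fold enrichment of a peak over its control is the authors' own value for that peak and was used to describe and rank peaks within a list and to compare overlapping peaks of the replicates. The median fold enrichment was 2.82 in replicate 1, 3.00 in replicate 2 and 2.96 in the replicated list. The replicated peaks covered 0.961 Mb, with a median width of 397 bp and a maximum of 4460 bp. Unless another list is named, peaks below are replicated peaks.

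Zinc finger genes of the Zfp series, which encode DNA-binding proteins including many KRAB repressors, carried H3K9me3 far more often than chance placement gave. Of 394 Zfp genes, 73 (18.5%) had a peak in the gene body or within 2 kb of it, against 8.28 expected (SD 3.35 over shifts), an 8.82-fold excess. The 173 peaks involved included strong ones at Zfp865, Zfp180, Zfp68 and Zfp146. Zfp865 on chromosome 7 held a peak of 2879 bp (5029550 to 5032428) over an exon and within 1 kb of an internal transcript start. Its fold enrichment was 5.27, with 5.27 and 4.73 in the overlapping peaks of replicates 1 and 2. Zfp180 on chromosome 7 held 4 peaks, the strongest over an exon at 24104541 to 24107495 with a fold enrichment of 4.92. Zfp68 on chromosome 5 held 9 peaks, the strongest in an intron at 138608076 to 138608337 with a fold enrichment of 4.67. Replicate 1 had no peak at that intronic position, although it had others in the gene. Zfp146 on chromosome 7 held 3 peaks, the strongest over an exon at 30161797 to 30163129 with a fold enrichment of 4.60. The two-sided permutation test by circular shifts gave p = 0.0002, the smallest that 10000 shifts can give, and an adjusted p of 0.0015 over the 15 gene lists. The excess was smaller in the longer lists: replicate 1's own list marked 135 Zfp genes against 58.9 expected (2.29-fold), replicate 2's own list 106 against 40.7 (2.60-fold) and the pooled list 153 against 69.2 (2.21-fold). Of the 73 genes with a replicated peak, 65 also had a peak of each replicate's own list anywhere in the gene or within 2 kb. Counting only replicated peaks that overlapped a peak in both own lists, 58 genes were marked, against 4.53 expected.

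Within Zfp genes the peaks often lay over the last exon, which usually encodes the zinc finger array. Of 155 pairs of a peak midpoint and a Zfp gene body, 73 (47.1%) fell in the last exon of the gene's longest coding transcript, against 14.6% (SD 2.72) when midpoints were redrawn evenly along the same gene. The 3.22-fold excess had a one-sided permutation p of 0.0001, the smallest that 10000 draws can give. These last-exon peaks belonged to 51 of the 71 genes with a midpoint inside the gene. The redraws treat neighbouring peaks in the same gene as independent, and no test counted over genes was run. They also treat all positions of a gene as equally able to give a peak, whatever their repeat or G+C content.

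Clustered protocadherin genes, which encode cell adhesion proteins and sit in tandem on chromosome 18, were the list with the highest share of marked members. A peak lay in or near 33 of 57 members (57.9%), against 1.5 expected (SD 4.6), a 22.0-fold excess. The gamma cluster held most of them. Pcdhga1, Pcdhga2 and Pcdhga3 each contained 33 peaks covering 21.3 kb, and Pcdhga4 contained 30 peaks covering 19.5 kb. These genes share their 3′ exons, so their annotated bodies overlap and the same peaks were counted for several of them. The 33 members rested on 43 distinct peaks. The strongest peak in the gamma cluster lay at 37743392 to 37743711, with a fold enrichment of 4.46 in the replicated list, 2.82 in replicate 1 and 5.05 in replicate 2. Other genes with the most bases under peaks were Pcdhgb1 (20.2 kb), Pcdhgb2 (18.95 kb), Pcdhga5 (18.7 kb) and the long annotated transcription units Gm42416 (28.9 kb), Gm37013 (28.5 kb) and Gm37388 (28.5 kb), which span the same region. The two-sided permutation test by circular shifts gave p = 0.0032 and an adjusted p of 0.016 over the 15 lists. The excess was 2.76-fold in replicate 1's own list (44 members against 15.9 expected), 3.75-fold in replicate 2's own list (42 against 11.2) and 2.90-fold in the pooled list (52 against 17.9). Of the 33 members, 31 had a peak of each replicate's own list anywhere in the gene or within 2 kb. Counting only replicated peaks that overlapped a peak in both own lists, 29 members were marked, against 0.893 expected.

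**Figure D1:**
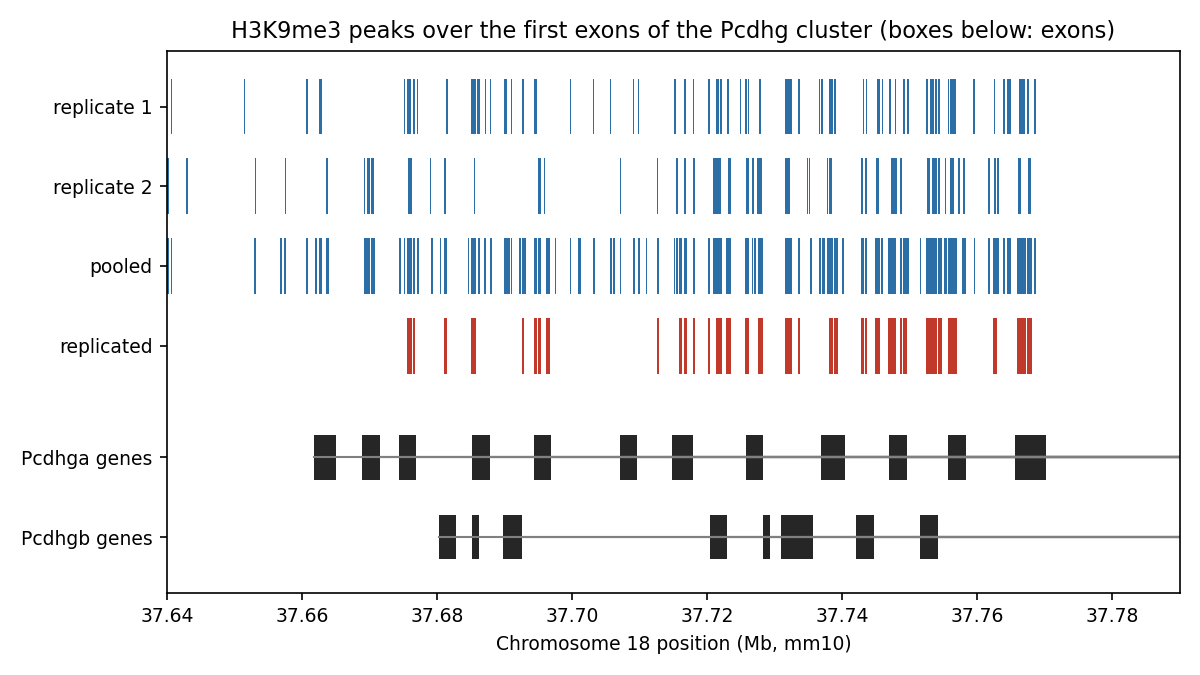
Peaks on chromosome 18 between 37.64 and 37.79 Mb (x axis, mm10 position) in each of the 4 peak lists (blue, and red for replicated peaks), above the exons (boxes) of Pcdhga and Pcdhgb genes. The 33 replicated peaks all end by 37768137; over the whole plotted region replicate 1 has 62 peaks and replicate 2 has 49.

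Imprinted genes, which are expressed from a single parental allele, also carried more peaks than chance placement gave. Of 48 members, 23 (47.9%) had a peak in the gene body or within 2 kb, against 1.82 expected (SD 1.45), a 12.7-fold excess. The Gnas locus on chromosome 2, which encodes the stimulatory G protein alpha subunit, had the strongest. A peak at 174285273 to 174286675 overlapped an exon of both Gnas and its antisense transcript Nespas, and lay within 1 kb of a transcript start of each. Its fold enrichment was 4.46, with 4.46 and 4.54 in replicates 1 and 2. Plagl1 on chromosome 10, a zinc finger transcription factor gene, had a peak at an internal transcript start (13090544 to 13091200) with a fold enrichment of 3.77. A peak at 143250758 to 143251499 on chromosome 7 lay in an intron of Kcnq1, a potassium channel gene, and over an exon of the non-coding Kcnq1ot1, with a fold enrichment of 3.52. Cdkn1c, which encodes a cell cycle inhibitor and lies in the same domain, had a peak within 1 kb of a transcript start with a fold enrichment of 3.26. A peak within 1 kb of the neighbouring starts of Peg3 and Usp29 had a fold enrichment of 3.41, with 2.15 in replicate 1 and 4.29 in replicate 2. The remaining imprinted genes named by rank were Impact (3.26), Blcap and Nnat (3.25 for the peak they share) and Sfmbt2 (3.11). Replicate 1 had no peak overlapping the Impact peak, and replicate 2 none overlapping the Blcap and Nnat peak. The two-sided permutation test by circular shifts gave p = 0.0002, the smallest that 10000 shifts can give, and an adjusted p of 0.0015 over the 15 lists. In replicate 1's own list 33 members were marked against 11.3 expected (2.93-fold), in replicate 2's own list 28 against 8.27 (3.38-fold) and in the pooled list 37 against 12.7 (2.92-fold). The 23 members rested on 25 distinct peaks, of which 6 lay at Gnas. Neighbouring members such as Peg3 and Usp29 shared peaks, so the members are not independent of each other. Of the 23 members, 22 had a peak of each replicate's own list anywhere in the gene or within 2 kb. Counting only replicated peaks that overlapped a peak in both own lists, 17 members were marked, against 1.07 expected.

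**Figure D2:**
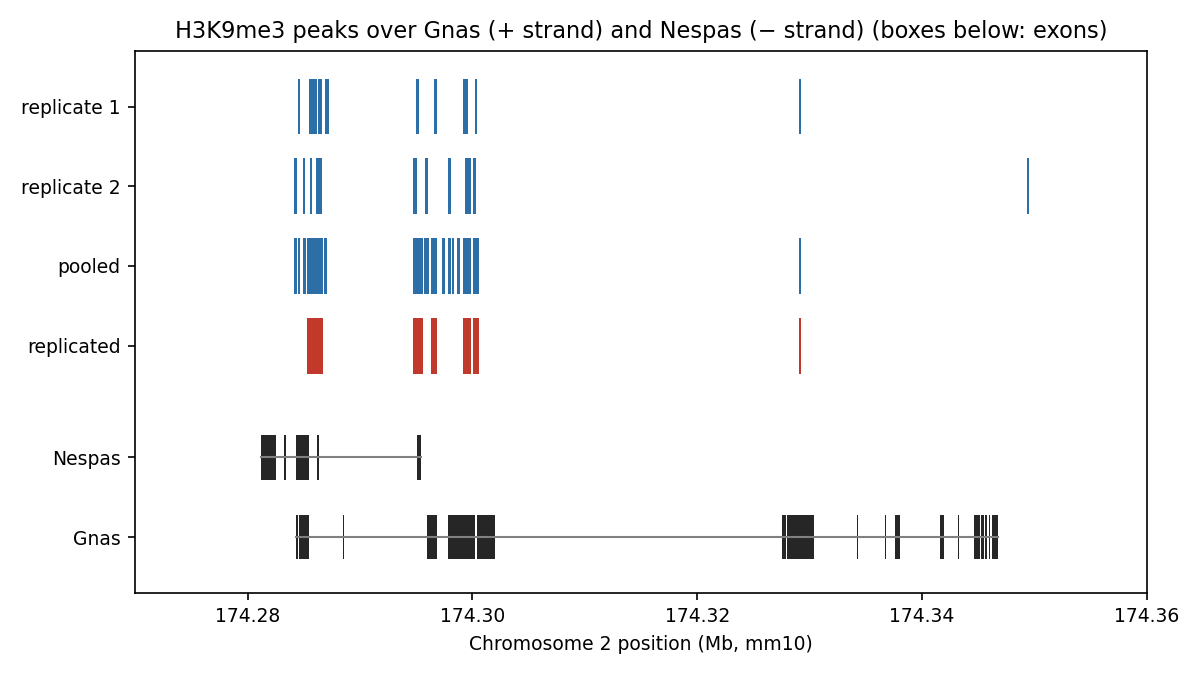
Peaks on chromosome 2 between 174.27 and 174.36 Mb (x axis, mm10 position) in each of the 4 peak lists (blue, and red for replicated peaks), above the exons (boxes) of Nespas and Gnas. Of the 6 replicated peaks, 5 lie in the upstream part of Gnas, where both replicates have peaks.

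No peak was found at any gene of 9 of the other 12 lists. These were the intestinal epithelium (37 genes), gut mesenchyme and smooth muscle (27), enteric nervous system (17), blood and endothelium (22), other organs (32), ribosomal protein (79), Hox (39), X-linked Rhox, Mage and Xlr (69) and H3K9 methylation machinery (24) lists. Shifted peaks gave between 0.235 and 0.596 marked members for these lists, so a depletion was not detectable with this number of peaks. The longer pooled list marked members of all these lists, for example 5 intestinal epithelium genes against 5.62 expected, and none passed the threshold. Olfactory receptor genes had 3 marked members of 1135, against 8.30 expected (SD 4.31), and the permutation test by circular shifts gave an adjusted p of 0.825. The strongest were upstream of Olfr1466 and Olfr212, each with a fold enrichment of 2.97. Vomeronasal receptor genes had 9 of 329 against 5.33 expected (SD 2.96; adjusted permutation p = 0.881), led by Vmn2r10 (3.38) and Vmn1r73 (3.25). Among 35 germline genes, Dazl, which encodes an RNA-binding protein of germ cells, was the only one marked, at its transcript start with a fold enrichment of 3.00. The Dazl peak had a counterpart in replicate 1 (3.15) and none in replicate 2. The Hox count depended on the list used: replicate 2's own list marked 9 Hox genes against 1.51 expected (adjusted two-sided permutation p = 0.0045), whereas replicate 1's own list marked 7 against 2.20 expected (adjusted permutation p = 0.114).

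**Figure D3:**
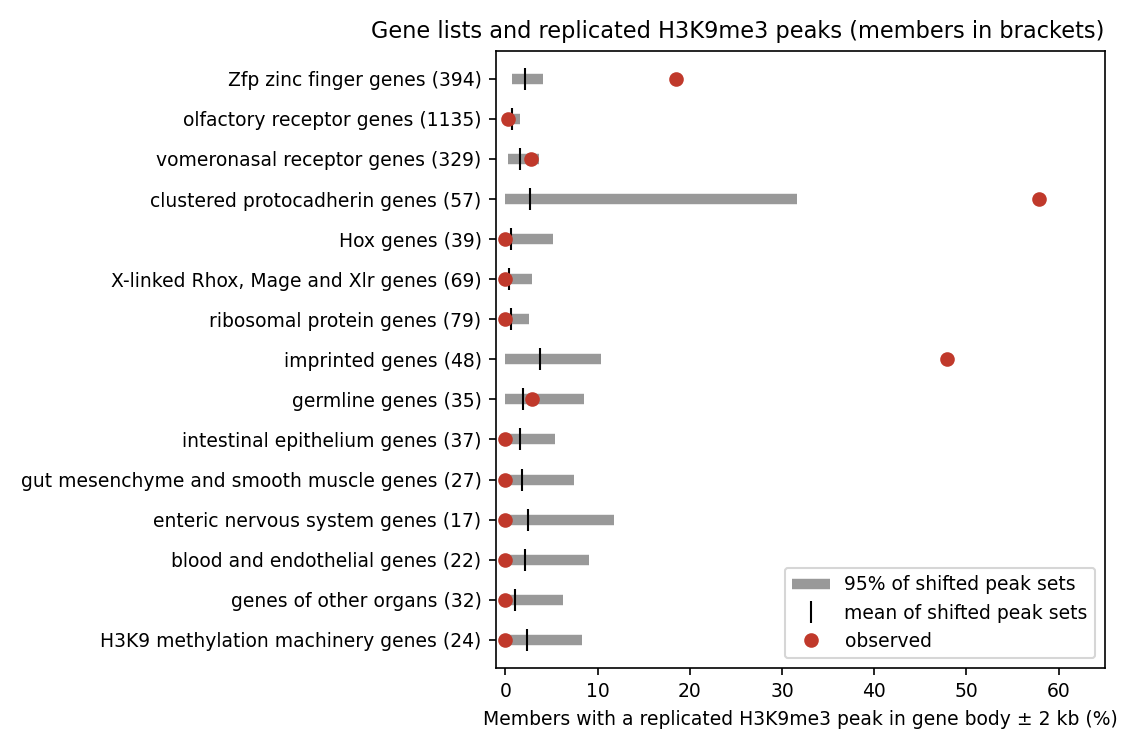
Percent of the members of each gene list (y axis, number of members in brackets) with a replicated peak in the gene body or within 2 kb (x axis). Red points are observed values, ticks the mean and grey bars the central 95% of 10000 shifted peak sets; the Zfp, clustered protocadherin and imprinted lists lie above their bars at 18.5%, 57.9% and 47.9%.

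Peak midpoints lay in exons and promoters of protein-coding genes more often than those of shifted peaks, although most were intergenic. Peaks over exons of Zfp and protocadherin genes are included, and shares without them were not computed. Of 1802 peaks on chromosomes 1 to 19 and X, 10.6% had their midpoint in an exon, against 2.84% expected (SD 0.474), and 6.99% lay within 1 kb of a transcript start, against 4.04% (SD 0.612). Introns held 26.4% against 35.1% (SD 2.45). For these 3 classes the two-sided permutation p was 0.0002, the smallest that 10000 shifts can give, and 0.000267 after adjustment over the 4 classes. The intergenic share of 55.99% lay within the spread of shifts around 58.0% (SD 2.67; adjusted permutation p = 0.452). The exon share was 4.40% in replicate 1's own list, 5.18% in replicate 2's own list and 4.35% in the pooled list, each against 2.84 to 2.86% expected. The promoter excess was tied to the replicated list. The promoter share was 3.98% in replicate 1's own list (adjusted permutation p = 0.884), 4.53% in replicate 2's own list (adjusted permutation p = 0.0542) and 3.92% in the pooled list (adjusted permutation p = 0.592). In these lists the intergenic share was above that of shifted peaks instead, at 62.1%, 60.5% and 63.2% (adjusted two-sided permutation p = 0.000267, 0.0192 and 0.000267). Replicated peaks averaged 48.5% G+C bases, against 42.0% for shifted peaks (SD 0.344), and 28.1% soft-masked repeat bases, against 33.8% (SD 1.08). Both differences had a two-sided permutation p of 0.002, the smallest that 1000 shifts can give. Shifts did not take into account how readily reads can be placed and peaks called in repeats. These differences therefore do not show that the mark itself avoids repeats.

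**Figure D4:**
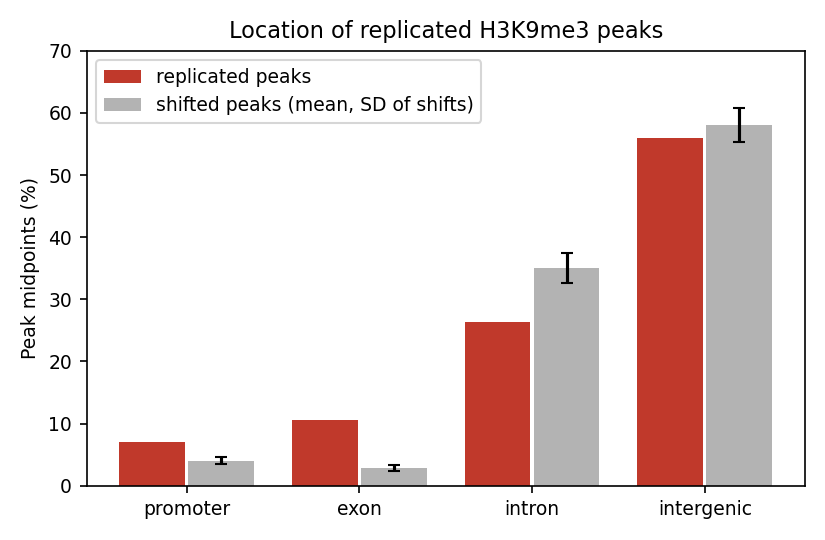
Percent of replicated peak midpoints (y axis) in promoters, exons, introns and intergenic sequence (x axis), beside the mean of 10000 shifted peak sets with their SD as error bars. Exons hold 10.6% against 2.84%, and introns 26.4% against 35.1%.

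Among protein-coding and imprinted genes, 120 had a peak within 1 kb of a transcript start. The highest fold enrichment was at Tcfl5, a helix-loop-helix transcription factor gene on chromosome 2, at 6.22, with 6.34 and 5.30 in replicates 1 and 2. Its peak of 1386 bp (180642696 to 180644081) overlapped the gene body by 13 bp and lay otherwise upstream. Klf14, a Krüppel-like factor gene on chromosome 6, had a fold enrichment of 5.81, with 6.10 in replicate 1 and 3.35 in replicate 2. After Zfp865 followed Asmt on chromosome X (5.17), which encodes the last enzyme of melatonin synthesis, and Polrmt on chromosome 10 (4.60, at an internal start), the mitochondrial RNA polymerase gene. Nphp4 on chromosome 4, a gene of the primary cilium, had a fold enrichment of 4.46 at an internal start. The last of the 10 starts ranked by rule, besides Gnas and Nespas, were those of the predicted gene Gm21887 on chromosome X (4.46) and of Zfp850 on chromosome 7 (4.33, at an internal start). All sampled 32-base words of the Gm21887 peak (100%) and 25.4% of those of the Asmt peak occurred more than once in the assembly. Replicate 1 had no peak overlapping the Zfp850 peak.

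The 5 windows of 1 Mb with the most bases under peaks held 12.9% of all bases covered on chromosomes. On chromosome 1, the window from 88000001 to 89000000 held 41 peaks covering 32.3 kb, all between 88204536 and 88310678. Of these, 20 peaks covering 16.8 kb lay in Mroh2a, 9 in Trpm8, the cold-sensing channel gene, and 8 in Ugt1a2, of which 7 also lay in Ugt1a1. These glucuronidation enzyme genes share 3′ exons, so their annotated bodies overlap. The protocadherin window on chromosome 18 (37000001 to 38000000) held 48 peaks covering 27.7 kb. On chromosome 4 (147000001 to 148000000), 41 peaks covering 18.96 kb were present, 25 of them (10.9 kb) in the long non-coding RNA gene C230088H06Rik. The window has 9 Zfp genes, of which Zfp933 held 4 peaks, Zfp985 3, and Zfp978 and Zfp984 1 each. On chromosome 17 (13000001 to 14000000), 25 peaks covering 17.5 kb included 10 (5.09 kb) in the long non-coding RNA gene 2700054A10Rik and 6 (8.73 kb) outside genes. Smok2a and Smok2b, genes of the sperm motility kinase family, held 5 peaks (2.32 kb) and 4 peaks (1.33 kb). On chromosome 11 (3000001 to 4000000), 16 peaks covering 16.6 kb included 8 in Sfi1 and 10 in Drg1, whose annotated bodies overlap. Windows were ranked by covered bases, not by fold enrichment. The highest fold enrichment in the chromosome 1 window was 2.81, below the replicated list's median of 2.96. In the other windows the highest was between 3.48 and 4.46. The same 5 windows ranked first in each replicate's own list. These windows were not compared here with a list of regions known to give artefact signal. The median share of repeated 32-base words per peak was 27.8% in the chromosome 4 window and 18.2% in the chromosome 17 window, against 0% on chromosomes 1 and 18.

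The replicates shared more peaks than chance gave, but most peaks of either were not called in the other. Of 9142 replicate 2 peaks on chromosomes 1 to 19 and X, 1036 (11.3%) overlapped a replicate 1 peak by at least 1 bp, against 0.27% for shifted peaks, a 42.0-fold excess. The one-sided permutation p was 0.0001, the smallest that 10000 shifts can give. Overlap rose with peak strength: with replicate 2 peaks split by p-value into 5 classes of equal size, 7.76% were overlapped in the weakest class and 23.5% in the strongest. Over the 1036 overlapping pairs, fold enrichment correlated across peaks with Spearman's rho of 0.32 (95% interval 0.26 to 0.37) and Pearson's r of 0.36. Peaks are not independent replicates, and no p was computed. With q of at most 0.01 required in both replicates, 23.0% of replicate 2 peaks were overlapped, and rho over the 104 pairs was 0.84.

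**Figure D5:**
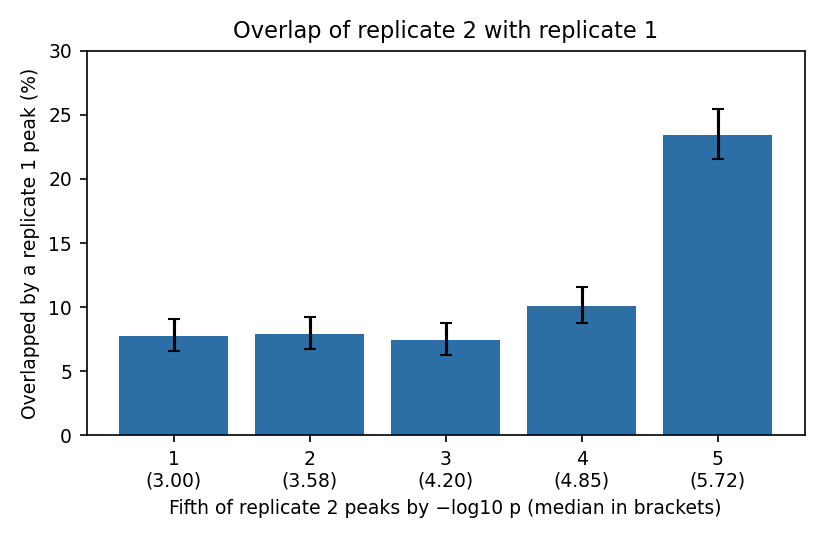
Percent of replicate 2 peaks overlapped by a replicate 1 peak (y axis) in 5 equal classes of replicate 2 peaks ranked by −log10 p (x axis, median in brackets), with exact 95% binomial intervals as error bars. The 4 weaker classes lie between 7.44% and 10.1% and the strongest at 23.5%.

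All 1948 replicated peaks were identical to a peak of the pooled list, which held 19060. Of them, 1132 (58.1%, exact 95% binomial interval 55.9 to 60.3%) overlapped a peak in each replicate's own list, 749 overlapped a peak of a single replicate and 67 overlapped neither. A q of at most 0.01 was reached by 58.9% of replicated peaks, 11.1% of pooled peaks, 3.55% of replicate 1 peaks and 5.82% of replicate 2 peaks. Replicated peaks were densest on chromosome 7 (1.41 peaks per Mb) and chromosome 17 (1.35), against 0.701 over chromosomes 1 to 19 and X together. The lowest density among these was on chromosome X (0.215).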

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

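The comparisons above used peaks on chromosomes 1 to 19 and X. Replicated peaks outside them are described below for places with more than 3, a limit for reporting that tests no expectation.

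On unplaced and unlocalised scaffolds lay 141 replicated peaks, 7.24% of the list, on 16 scaffolds, with 45 on a single scaffold. Of these, 136 were on unplaced scaffolds. The unplaced contigs of the reference total 0.804 Mb, which makes 169 peaks per Mb, 241 times the density on chromosomes 1 to 19 and X. Both replicates' own lists had such peaks, 207 in replicate 1 and 201 in replicate 2. Reads shared between near-identical copies were tested as an explanation by the share of 32-base words that occur more than once. Its median over the 22 unplaced contigs was 35.2% (range 10.2 to 77.1%), above the 2% of replicated peaks on chromosomes but below the 50% set for this explanation and above the 20% set against it. Shared reads and a true excess of H3K9me3 on these scaffolds therefore cannot be told apart, since scaffold names could not be paired with sequences and copies missing from the assembly are not counted. No biological explanation was tested.

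Chromosome Y carried 5 replicated peaks, 4 of them between 90739058 and 90742634, with fold enrichments of 2.49 to 3.99 and repeated 32-base words of 21.8 to 51.1% over the 5. Their density was 0.055 peaks per Mb, below the 0.701 of chromosomes 1 to 19 and X.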

How the results depend on the processing

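The Zfp, clustered protocadherin and imprinted lists stayed past the threshold under all 10 alternatives, but in each replicate's own list and the pooled list their excess fell from 8.82, 22.0 and 12.7-fold to 2.21 to 2.60, 2.76 to 3.75 and 2.92 to 3.38-fold. The exon share there was 4.35 to 5.18%. Of 208 alternative values of 30 results, 192 counted as unchanged. Tested results counted if they kept their side of the threshold and, where past it, their direction. Results not past it could change direction, as for olfactory receptor genes (3 against 8.30 expected, and 98 against 82.1 in the pooled list). Covered length has no test or error, and counted as unchanged within a factor of 1.5. Other values without a test counted if equal or within the stated error. Among fold enrichments at named genes with a replicate left out, 35 values moved and 35 did not, with a peak shared by several genes counted for each. A value counted as moved if it differed by more than the SD of the replicates' values, or if a replicate had no overlapping peak. Wide disagreement between replicates can therefore count as not moved, as at Peg3 (3.41, against 2.15 in replicate 1). The alternatives chosen after seeing the data were peaks on unique sequence, peaks present in each replicate's own list, and gene sets matched on length and G+C content. At q of at most 0.01, covered length fell to 215.9 kb in replicate 1, 225.0 kb in replicate 2, 873.6 kb in the pooled list and 617.7 kb in the replicated list, since fewer peaks remained, and rho between replicates was 0.84. With at least 50% of both peaks overlapping, rho was 0.39, and 32.1% of replicated peaks were in both own lists. In the pooled list, promoters held 3.92% and intergenic sequence 63.2% of peaks, and 71 vomeronasal receptor genes were marked (adjusted permutation p = 0.0427). Leaving out each replicate in turn gave 3.98 to 4.53% in promoters, 60.5 to 62.1% in intergenic sequence and 7 to 9 Hox genes. Against sets matched on length and G+C content, the 3 marked olfactory receptor genes were fewer than the 9.44 expected (SD 2.35, adjusted permutation p = 0.0127). Those sets were drawn gene by gene and do not keep the spacing of genes. The test by circular shifts, which keeps it, had an SD of 4.31 and an adjusted permutation p of 0.825. The matched result alone therefore does not show a depletion. The cause of these changes between settings was not tested. No paired analysis was possible because the series has a single group. Depth is unknown, and lists with fewer than 0.6 expected members cannot show depletion.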

Other observations

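The test from means of repeated words was chosen only after its medians had been seen. The test of replicate 2 peaks at q of at most 0.01 and the test of chromosome ends were written before their own values but after overlap by peak strength and the dense windows had been seen.

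Replicated peaks were frequent at the ends of some chromosomes. The first assembled 1 Mb of chromosomes 1 to 19 and X, next to the centromere in mouse, held 87 replicated peaks against 13.4 expected (SD 9.62), on 11 chromosomes and none on the others, with the most on chromosomes 4 (19 peaks), 16 (18) and 11 (16). The two-sided permutation test by shifts gave an adjusted p of 0.0016 over 4 such tests. The last 1 Mb held 63 against 13.2 expected (adjusted permutation p = 0.0144). A hypothesis was that heterochromatin next to the centromere reaches into the assembled sequence. Among peaks on unique sequence the first 1 Mb held 49 against 10.2 expected, a 4.79-fold excess (adjusted permutation p = 0.0245). This repeats the excess on part of the same peaks, and the last 1 Mb, which the hypothesis does not name, had an excess as well, so the hypothesis stays open. The last 1 Mb had a 2.62-fold excess among those peaks (adjusted permutation p = 0.0558), and the difference between the ends was not tested. Copies missing from the assembly, which word counts cannot see, stay open, and the chromosome ends were not compared here with a list of regions known to give artefact signal.

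A scan of 274 protein-coding gene families by symbol, each with at least 10 members, was run without a prior choice of families. The Zfp and Pcdhb families passed the adjusted threshold, both at an adjusted permutation p of 0.0274, and both belong to lists fixed in advance. Each had a permutation p of 0.0002, the smallest that the shifts can give. Over 274 families, a family at this p with no other near it could not have passed. Families that did not pass are therefore not shown to lack an excess. The Zfp family was the same 394 genes as the fixed list, on the same peaks, so its pass repeats the earlier result. Pcdhb genes had 6 marked of 22 against 0.059 expected. The Ugt family had 9 marked of 22 against 0.557 expected, all in the Ugt1a cluster, where overlapping bodies share peaks (permutation p = 0.0126, adjusted 0.863). Pcdhga genes, whose bodies also overlap, had 12 marked of 12 against 0.457 expected (permutation p = 0.0476, adjusted 1).

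The excess at Zfp, imprinted and clustered protocadherin genes was weighed against 2 technical explanations. Reads shared between near-identical copies would lower the excess among peaks on unique sequence, but it was 9.29-fold for Zfp genes (permutation p = 0.0002), 15.1-fold for imprinted genes (permutation p = 0.0002) and 25.1-fold for protocadherins (permutation p = 0.0018). Words were matched exactly within the assembly, here and in the test of replicates below. Copies that differ within a word, or are missing from the assembly, can therefore pass as unique. Gene sets matched on length and on G+C content around the gene start left a 6.30-fold excess for Zfp genes, 12.3-fold for imprinted genes (19 of the 40 protein-coding members marked) and 7.58-fold for protocadherins, each with a permutation p of 0.0002, the smallest that 10000 draws can give. The matched sets treat genes as independent, which nested protocadherin bodies and imprinted genes that share a peak are not. They match G+C at gene starts, not at last exons. No biological explanation was tested, since the series has 1 group.

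Most peaks of either replicate were absent from the other. If weak peaks near the calling threshold were the reason, strong peaks would overlap: the ratio of overlap between the strongest and weakest of 5 classes was 3.02 (95% interval 2.53 to 3.61), which met the ratio of 3 set for it. Of 452 replicate 2 peaks at q of at most 0.01, 46.2% were overlapped by a replicate 1 peak of any strength (exact 95% interval 41.6 to 51.0%). This was below the 50% set for the explanation, against 9.52% of the other replicate 2 peaks. The ratio reached its set value and the share fell short of its own, but both set values lay inside the 95% intervals. The explanation by weak peaks therefore stays open, as do differences between the controls and between the pools, which were not tested. For reads shared between near-identical copies, the prediction set was more repeated words in peaks without a counterpart. The mean share was instead lower without a counterpart, at 4.34% against 8.92%, a difference of -4.58 percentage points (95% interval -5.64 to -3.52). Shared reads that recur at the same place in both replicates would give a difference in this direction too, so the test does not decide on shared reads. The median difference of 0 percentage points decides nothing either, since both medians were at the floor of 0%.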
